A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

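RNA of 6 samples of S. pombe was measured on Affymetrix Yeast Genome arrays, 2 for each of empty vector, Spc1 and Spc1K49R. Total RNA was extracted and biotin-labelled cRNA prepared by the manufacturer's protocol, per the labels. The deposited value table holds log2 values that the authors had normalized between arrays by a method not given in the sources used here. The log base was inferred, since differences between columns matched the log2 fold changes of the deposited comparison tables. In all 9133 probe sets the median over the 6 arrays was 0, so each probe set had been centred by the authors and its level is unknown. Centring leaves differences between arrays as they were, but tends to make correlations between arrays negative. It rules out a filter on dim probe sets, a fresh quantile normalization and a trend of variance with intensity.

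The authors also deposited 3 comparison tables, with a fold change, its log2 and an unadjusted p-value for each probe set. Per the file headers, probe sets between the 10th and 100th percentile of raw signal were kept, a moderated test with asymptotic p-values was used at 0.05, and no correction for multiple testing was made. These tables were used as deposited, for description and for names. Their values differ slightly from differences of the value table, by a median of 0.0763 log2 units for mutant B against wild type and 0.0493 for mutant C against wild type. They also hold group means, in 6 columns, which were not used. Mutant B, mutant C and wild type were matched to Spc1, Spc1K49R and empty vector only by the agreement of fold changes.

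Names came from the deposited tables alone, which name 215 probe sets, 76 of S. pombe, 116 of S. cerevisiae and 23 controls. Of the S. pombe probe sets 72 had 1 gene and 4 several, and 74 were matched to a gene table of assembly ASM294v3, used for current symbols only. The genome build behind the array was not given in the sources used here, so no coordinates are printed. The species of the remaining probe sets was not known here, so all probe sets other than controls were tested together, as set out for this case before the data were examined.

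Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, in a single model of all 6 arrays with a mean per group and 3 residual degrees of freedom. The 3 contrasts were Spc1 minus empty vector, Spc1K49R minus empty vector and Spc1K49R minus Spc1. P-values were adjusted by the Benjamini-Hochberg method over 8960 probe sets for each contrast, with a threshold of 0.05. A two-sided exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is reported for single genes. The labels call the arrays biological replicates and say nothing more of how the cultures were separated. The model was tested on simulated data with 200 changed probe sets of known fold. With the spread of these 6 arrays, 0% of the 2-fold changes were recovered both for Spc1 and for Spc1K49R against empty vector. With the smaller spread of the 2 Spc1K49R arrays set on all 6 arrays, 100% were recovered in both, with 13 and 6 false calls.

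Genes were named per comparison by a rule written before the data were examined, apart from those marked as chosen after their values were seen. It took sty1, a set of pathway and cell cycle genes, and the probe sets with the largest changes past the threshold. It also took up to 4 members of each gene list. Where fewer than 5 probe sets passed, the 12 with the smallest p were given as not passing. All 7 named members of the mating list are given for Spc1K49R, more than the 4 of the rule. A test of the gene lists with camera had been planned. It was not run, because the only members with names were those the study had selected on these arrays, and the lists were counted instead. Random sets of probe sets with the same order of the Spc1K49R and empty-vector arrays were drawn for comparison with the mating genes. The mating list holds 26 genes, 23 of them found in the gene table.

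Array quality was read from control probe sets, which were not part of the tests. The 5' minus 3' difference is the mean over 6 S. pombe control genes of the 5' value minus the 3' value. Poly-A controls comprised 35 probe sets and hybridization controls 27. The correlation and covariance of the differences from empty vector were compared with 100 simulations of unchanged groups. These drew each group independently and kept each probe set's spread between the 2 arrays of a group. The overlap of the deposited lists was set beside lists of the same lengths from such simulations, ranked by the difference over its spread, which only approximates the authors' selection and was added after the data were seen. Alternatives covered centring of arrays, robust variances, array weights, the replicate number as a block, the arrays entering the fit, the thresholds and each array left out in turn. Alternatives chosen after seeing the data were the removal of Spc1 replicate 1 and Spc1K49R replicate 2, the 5' minus 3' difference as a covariate, unadjusted p-values and the testing of control probe sets. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.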

Results

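Messenger RNA was measured in the fission yeast Schizosaccharomyces pombe carrying an empty vector, overexpressing Spc1, or overexpressing Spc1K49R, a form named for a lysine to arginine substitution. Spc1, also called Sty1 and encoded by the gene sty1, is the MAP kinase that relays environmental stress to transcription factors and to the cell cycle machinery. Each of the 3 groups held 2 arrays labelled as biological replicates, so 6 arrays were available, and this number limits the precision of every value. The array type carries probe sets for S. pombe and for the budding yeast Saccharomyces cerevisiae, and 8960 probe sets remained after 173 control probe sets were set aside. The cells were S. pombe, so S. cerevisiae probe sets were taken as background. Whether any of them read a similar S. pombe transcript or a plasmid gene was not tested. Most probe sets could not be told apart by species here, so counts and correlations over all probe sets include S. cerevisiae ones. Values are log2 signals relative to the median of the 6 arrays for each probe set, so they show differences between arrays and give no absolute level. Only 189 of the 8960 probe sets had a name in the files used here, all of them from the authors' deposited tables of differences. The named genes were therefore already picked by the study on these same arrays.

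The first question was whether the overexpressed gene itself was higher in the cells labelled as overexpressing it. For sty1 the log2 values were -1.07 and -1.04 with empty vector and 1.04 and 1.49 with Spc1. The array labelled Spc1K49R replicate 1 had 1.20, whereas the array labelled Spc1K49R replicate 2 had -1.37, below both empty-vector arrays. The mean with Spc1 was 1.26 ± 0.32 (SD, n = 2) against -1.06 ± 0.02 (SD, n = 2) with empty vector, a log2 difference of 2.32 with a standard error of 0.83. With limma this difference had an adjusted p of 0.79 over all probe sets and an unadjusted p of 0.0383. The standard error is shared by the 3 groups and includes the spread between the Spc1K49R arrays. With only the 4 arrays of Spc1 and empty vector, limma gave an unadjusted p of 0.000584 and an adjusted p of 0.951. The authors' deposited table gives sty1 as 5.39-fold higher with an unadjusted p of 0.00066. For Spc1K49R the mean of -0.09 ± 1.81 (SD, n = 2) exceeded that of the empty vector by 0.97, less than the spread between its own arrays. That difference was 2.25 without the array labelled Spc1K49R replicate 2 and -0.31 without Spc1K49R replicate 1. Every direction given below for Spc1K49R draws on an array whose sty1 value goes against its label.

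**Figure D1:**
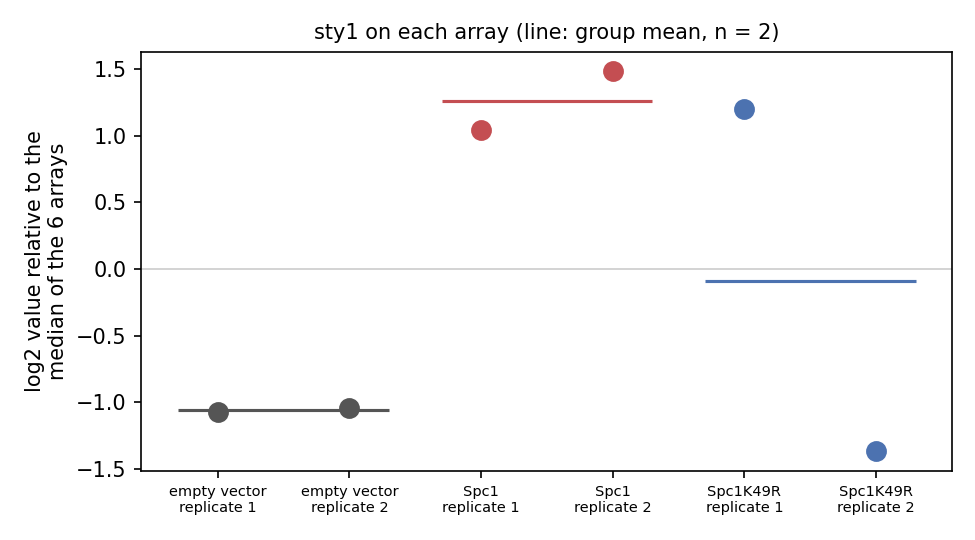
The vertical axis shows the log2 value of sty1 relative to the median of the 6 arrays, each point is an array and each line the mean of the 2 arrays of a group. Both Spc1 arrays (1.04 and 1.49) and Spc1K49R replicate 1 (1.20) lie above the empty-vector arrays, and the array labelled Spc1K49R replicate 2 (-1.37) lies below them.

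The arrays also differed in the state of the RNA they showed. On Spc1 replicate 1 the values over all tested probe sets had an SD of 0.82, against 0.11 to 0.31 on the other arrays, and 1565 probe sets lay 1 or more log2 units from the median of the 6 arrays. The actin gene act1, which has control probe sets along its length, read -2.66 at its 5' end, -1.55 in the middle and -0.37 at its 3' end on this array. Over 6 S. pombe control genes the mean 5' minus 3' difference was -1.53 on Spc1 replicate 1 and between -0.56 and 0.40 on the other 5 arrays. Empty vector replicate 1 came next, with -0.56, an SD of 0.31 and 139 probe sets that far from the median. Across probe sets it correlated at 0.39 with Spc1 replicate 1 and at -0.52 with empty vector replicate 2. Centring of the values tends to make such correlations negative, so they do not compare whole profiles. The root mean square difference, which centring leaves as it was, was 0.782 from Spc1 replicate 1 and 0.414 from empty vector replicate 2. Empty vector replicate 1 enters both comparisons with empty vector. The 35 probe sets for poly-A control transcripts had a median of 5.28 on Spc1 replicate 1 and 1.35 on Spc1 replicate 2, and at most 0.16 elsewhere.

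**Figure D2:**
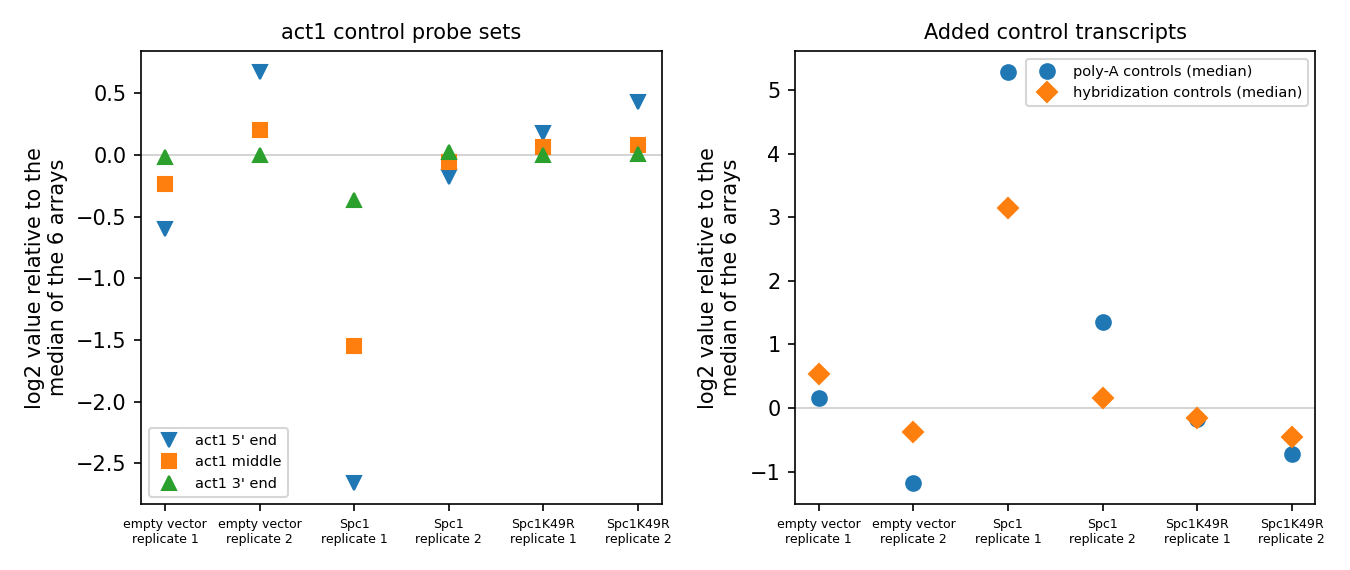
The left panel shows the log2 values of the act1 control probe sets at the 5' end, middle and 3' end on each of the 6 arrays, and the right panel shows the median log2 value of the poly-A and hybridization control probe sets. Spc1 replicate 1 has the lowest act1 5' value (-2.66) and the highest poly-A control median (5.28).

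With Spc1, 20 of the 23 S. pombe probe sets in the authors' deposited table against wild type had both Spc1 arrays below both empty-vector arrays, and 3 had them above. The study selected these probe sets on the same arrays, which makes groups that do not overlap nearly certain. Over all tested probe sets 945 had both Spc1 arrays above and 1288 below, together 24.9% where chance gives 33.3%. The 20 lower probe sets had a median of -0.62 on Spc1 replicate 1 and -0.32 on Spc1 replicate 2, against 0.26 and 0.12 with empty vector. The first of these Spc1 arrays is the array with the low 5' values, and 18 of the 20 were lower on it than on replicate 2. Among the 12 probe sets with the smallest p, aph1, which encodes a diadenosine tetraphosphate hydrolase, differed by -0.59 (SE 0.13), and its Spc1 values were -0.45 and -0.42. The uracil-regulated gene urg2 differed by -0.94 (SE 0.24) and car1, which encodes arginase, by -0.72 (SE 0.21). The shared probe set of meu1 and meu2 differed by -1.25 (SE 0.32), SPAC750.08c by -0.69, SPCC162.01c (snp27) by -0.60, SPAC19A8.14 (pth2) by -0.48 and SPCC1450.07c (dao1) by -0.48. The 2 named S. pombe genes of these 12 with higher values were SPAC22H10.06c, at 0.78 (SE 0.15), and mam3, a mating agglutinin gene, at 0.59 (SE 0.16). The other 2 of the 12 were the S. cerevisiae probe set RIO2 and an unnamed probe set.

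None of these differences passed the test. With limma 0 of 8960 probe sets had an adjusted p under 0.05 between Spc1 and empty vector, and the smallest adjusted p was 0.79. At an unadjusted p under 0.05 there were 108 probe sets, 45 higher and 63 lower, where 448 would be expected by chance if all arrays had an equal spread. That count was 39 without empty vector replicate 1, 224 without Spc1 replicate 1, 4066 without Spc1 replicate 2 and 17 without either Spc1K49R array. When Spc1 replicate 2 was left out, so that Spc1 replicate 1 stood alone, 2968 probe sets passed, 916 of them higher. In simulated data with the spread of these arrays, 0% of 200 probe sets with a 2-fold change were recovered in this comparison and 92.5% of 200 with a 4-fold change. Those data gave all probe sets of an array the same spread, which real probe sets do not have. A 4-fold change can therefore not be taken as detectable here, and sty1, with a log2 difference of 2.32, did not pass.

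Of the 26 genes of the mating list, 7 had a name, and these 7 had both Spc1K49R arrays above both empty-vector arrays. None of them passed with limma, and 1 of the Spc1K49R arrays lacked raised sty1. The 7 were mfm1 and mfm3, which encode precursors of the M-factor pheromone, mam2, the receptor gene for P-factor, mam3, rgs1, a regulator of G-protein signalling, spk1, the pheromone MAP kinase gene, and mei2, an RNA-binding regulator of meiosis. The log2 difference was 0.51 (SE 0.19) and 0.52 (SE 0.20) for the 2 probe sets of mfm1, 0.52 (SE 0.20) for mei2, 0.56 (SE 0.26) for mam2 and 0.47 (SE 0.31) for rgs1. It was 0.31 for mfm3, 0.31 for spk1 and 0.26 for mam3. Without empty vector replicate 1 it was 0.28 and 0.30 for mfm1 and 0.32 for mei2, and without Spc1K49R replicate 1 it was 0.35 for mam2. Because the study picked these genes on these arrays, their number is not independent evidence of a direction. With the 2 probe sets of mfm1 averaged, Spc1 replicate 2 was above the empty-vector mean for 7 of these genes and Spc1 replicate 1 for 4. For mfm1 Spc1 replicate 1 had -0.11 and -0.29 on its 2 probe sets, either side of the empty-vector mean of -0.14 on both. Of 124 other probe sets with both Spc1K49R arrays above both empty-vector arrays and a difference of 0.26 to 0.56, 92.7% had Spc1 replicate 2 above the empty-vector mean and 41.1% had Spc1 replicate 1 above it. The mfm genes are close copies, and signal can be shared between their probe sets.

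Other S. pombe genes among the 12 smallest p for Spc1K49R were SPAC22H10.06c, at 0.45 (SE 0.15), SPAC11D3.09, at -0.40 (SE 0.15), and probe sets shared by SPAC212.08c and SPAC750.07c, at 0.51, and by 4 genes of the SPBPB10D8 cosmid, at -0.47. The S. cerevisiae probe sets YOR378W and SMD1 and 3 unnamed probe sets completed the 12. Larger differences, chosen after their values were seen, were those of SPCC569.02c, at 0.84 (SE 0.63), and for3, a formin gene of actin cables, at 0.64 (SE 0.67). The first was 0.47 without empty vector replicate 2, and for3 was 0.34 without empty vector replicate 1 and 0.32 with the 5' minus 3' difference as a covariate. The probe set of SPAC212.08c and SPAC750.07c was 0.30 without empty vector replicate 2. With limma 0 of 8960 probe sets had an adjusted p under 0.05, and the smallest adjusted p rounded to 1. At an unadjusted p under 0.05 there were 8 probe sets, 5 higher and 3 lower, against 448 expected by chance if all arrays had an equal spread. The standard errors here include the spread of the Spc1 arrays, with an SD of 0.82 on Spc1 replicate 1, which raises the p-values. On the log2 scale 20 probe sets differed by 1 or more. In simulated data with the spread of these arrays, 0% of 200 probe sets with a 2-fold change were recovered in this comparison and 96.5% of 200 with a 4-fold change. Those data again gave all probe sets of an array the same spread, so the recovery does not carry over to real probe sets. The count at an unadjusted p under 0.05 was 92 without either Spc1 array, 12 without empty vector replicate 1, 137 without empty vector replicate 2, 0 without Spc1K49R replicate 1 and 9 without the array labelled Spc1K49R replicate 2.

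**Figure D3:**
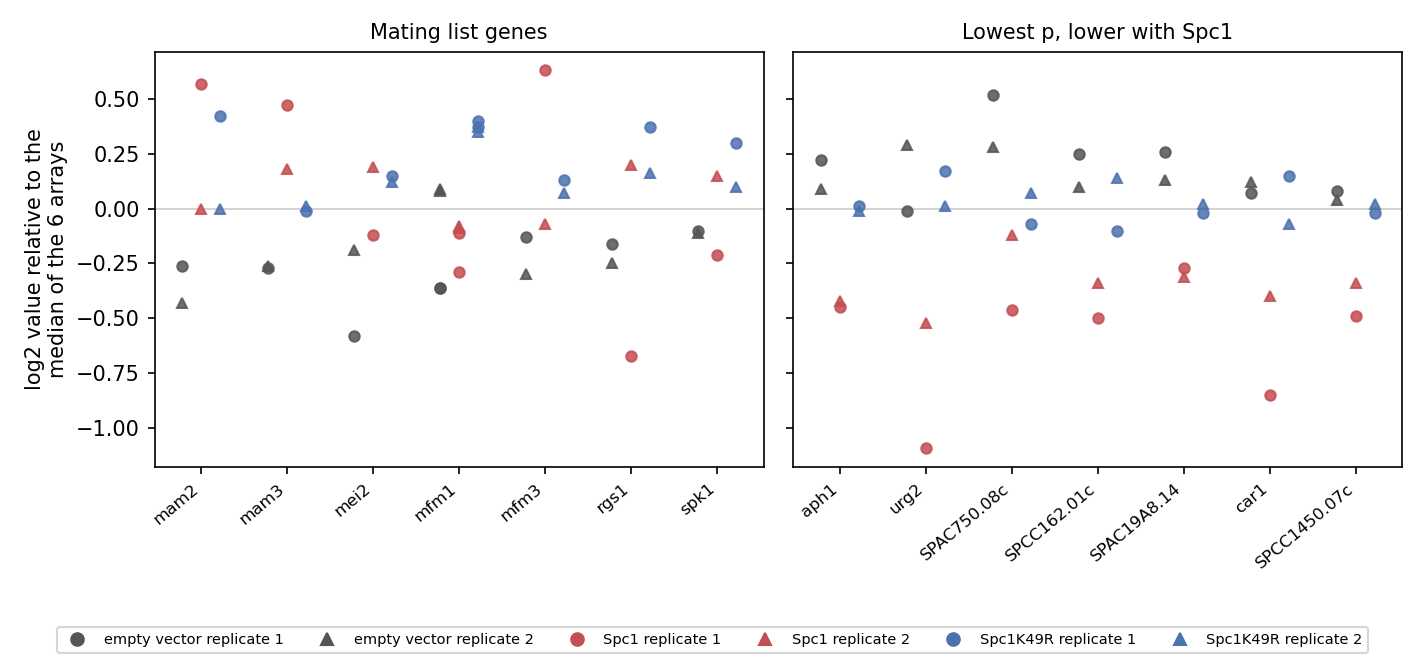
The vertical axis shows log2 values relative to the median of the 6 arrays for 7 mating list genes (left) and for 7 single genes with values lower with Spc1 among the 12 smallest p (right), with circles for replicate 1, triangles for replicate 2 and a colour per group. Both Spc1K49R arrays lie above both empty-vector arrays for the 7 mating genes, and both Spc1 arrays lie below both empty-vector arrays for the genes on the right, such as aph1 at -0.45 and -0.42.

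Spc1K49R was then set directly against Spc1, which is also the test of whether the effects of the 2 forms differ. It uses the same Spc1 arrays as the first comparison, so a low value with Spc1 enters both. The shared probe set of meu1 and meu2 was higher with Spc1K49R by 1.06 (SE 0.32), urg2 by 0.90 (SE 0.24), SPAC14C4.01c (atg43) by 0.79 (SE 0.21) and SPBC25H2.10c (tan1) by 0.65 (SE 0.19). Against empty vector the Spc1K49R difference was -0.19 (SE 0.32) for meu1 and meu2 and -0.05 (SE 0.24) for urg2. With the 5' minus 3' difference as a covariate, chosen after seeing the data, the difference from Spc1 was 0.54 for urg2, 0.49 for SPAC14C4.01c and 0.41 for SPBC25H2.10c. The probe set of meu1 and meu2 was at 0.70 without Spc1 replicate 1. Without that array and the array labelled Spc1K49R replicate 2 it was at 0.605 and SPAC14C4.01c at 0.46. Of the 28 S. pombe probe sets in the authors' deposited table of mutant B against mutant C, 19 had both Spc1K49R arrays above both Spc1 arrays and 9 below. The study selected these on the same arrays, which makes groups that do not overlap nearly certain. Over all tested probe sets 1936 lay above and 1296 below, together 36.1% where chance gives 33.3%. The other named probe sets among the 12 smallest p were the S. cerevisiae probe sets RIO2, at 0.58, BRR6, at -0.53, CPA1, at -0.51, LSM7, at -0.60, and YPL119C-A, at -0.62, or -0.37 with the covariate and -0.35 without those 2 arrays. With limma 0 of 8960 probe sets had an adjusted p under 0.05, and the smallest was 0.717. At an unadjusted p under 0.05 there were 91 probe sets, 46 higher and 45 lower. That count was 33 without either empty-vector array, 141 without Spc1 replicate 1, 4262 without Spc1 replicate 2, 3 without Spc1K49R replicate 1 and 13 without the array labelled Spc1K49R replicate 2. Without Spc1 replicate 2, 3234 probe sets passed, 2211 of them higher.

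The Spc1 and Spc1K49R differences from empty vector shared 0 probe sets past the threshold, since neither comparison had any with limma. Across probe sets, which are not independent replicates, their log2 differences had a Pearson correlation of -0.05 and a covariance of -0.00363. Simulated unchanged groups against the same empty-vector arrays gave a mean correlation of 0.39 and a mean covariance of 0.0431 over 100 simulations. The observed correlation was 0.43 without empty vector replicate 1, 0.32 without empty vector replicate 2 and 0.64 without Spc1 replicate 1, where the simulation gave 0.53, 0.53 and 0.29. The covariance in those settings was 0.0338, 0.0447 and 0.0242, below the simulated 0.0856, 0.0851 and 0.0427. Without Spc1 replicate 1, 67.9% of probe sets had the same sign in both comparisons, where the simulation gave 61.2%. With an array left out, the simulation still took the spread from both arrays of its group. The wide spread of Spc1 replicate 1 thus stayed in the simulation and lowered its correlation and sign share. No likeness can be read from the higher observed correlation and sign share there, and the covariance lay below the simulated value. Without empty vector replicate 1, its spread likewise stayed in the simulated covariance. The simulations also drew the groups independently, whereas deviations of replicate 1 from the group mean correlated at 0.47 between empty vector and Spc1. Covariances below the simulated values can therefore not be read as a difference between the 2 effects. With 2 empty-vector arrays the controls could not be split into sets of 2.

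Of 29 gene lists fixed before the data were examined, 20 had no named member, 7 had 1 or 2 and 2 had 3 or more. No member passed with limma in any comparison. The Spc1 pathway, the ribosomal proteins, the oxidative stress genes and the cell wall genes were among the 20 without a name, and of the pathway and cell cycle genes fixed in advance for naming only sty1 had a named probe set. The core stress response list had SPBC23G7.10c, at -0.27 (SE 0.15) with Spc1K49R against empty vector, and at -0.17 without empty vector replicate 1. The mitotic entry list had nif1, the gene of an inhibitor of the kinase Cdr1, higher by 0.48 (SE 0.17) with Spc1K49R than with Spc1, and by 0.28 without Spc1 replicate 1 and the array labelled Spc1K49R replicate 2. The meiosis list had rec8, a meiotic cohesin gene, at -0.63 (SE 0.25) with Spc1 against empty vector, and spo6, at -0.83 (SE 0.37) with Spc1K49R against Spc1, or -0.37 with the 5' minus 3' covariate. The subtelomeric list had 4 members. With Spc1K49R against empty vector SPAC750.08c was at -0.40, SPAC869.02c (yhb1) at -0.53, ranging from -0.79 to -0.26 without an empty-vector array, and dak2 at 0.36, and SPBPB2B2.08 was at -0.81 with Spc1K49R against Spc1, or -0.42 with that covariate. The glucose-repressed list shared dak2 and SPBPB2B2.08 with it. The nitrogen starvation list had SPAC1039.08, at -0.48 (SE 0.17) with Spc1, the flocculation list mbx2, at 0.29 (SE 0.23), and the amino acid list arg7, at -0.22 (SE 0.22), both with Spc1K49R. All of these members come from the study's own selection on these arrays.

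The authors' deposited tables name their groups mutant B, mutant C and wild type. Their log2 differences had a correlation across probe sets of 0.995 for mutant B against wild type with Spc1 minus empty vector, of 0.974 for mutant C against wild type with Spc1K49R minus empty vector, and of 0.999 for mutant B against mutant C with Spc1 minus Spc1K49R. Mutant B against mutant C also correlated at 0.98 with Spc1 minus empty vector. Its median absolute difference was 0.178 log2 units there and 0.0252 from Spc1 minus Spc1K49R. Mutant B against wild type correlated at 0.929 with Spc1 minus Spc1K49R. Its median absolute difference was 0.231 there and 0.0763 from Spc1 minus empty vector. Control probe sets were included. The largest S. pombe differences in the table of mutant B against wild type, chosen after their values were seen, were sty1 at 2.43, SPAC27D7.09c at -1.37 and mug124 at -1.27. In the limma fit SPAC27D7.09c was at -1.37 and mug124 at -1.36, and without Spc1 replicate 1 they were at -0.85 and -0.76. The table of mutant C against wild type held 132 probe sets, of which 35 were S. pombe, 92 S. cerevisiae and 5 control probe sets. S. cerevisiae probe sets, which were taken as background, made up 69.7% of that table and 81.2% of its lower part. Their share among all probe sets was not known here. In the table of mutant B against wild type they made up 16.7% of 42 probe sets, and 12 of the 20 higher probe sets were controls. The tables of the mutants against wild type shared 4 probe sets apart from controls, all 4 in the same direction. Both tables used the same wild-type arrays, and lists of the same lengths, 30 and 127, from 100 simulations of unchanged groups against shared empty-vector arrays shared a mean of 4.32 in the same direction.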

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

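All tests weighed here were chosen after the results they bear on, or values closely tied to them such as the correlations between arrays, had been seen. They can argue against an explanation and cannot establish any.

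Control probe sets, which took no part in the comparisons, gave a signal on Spc1 replicate 1 above the empty-vector arrays. The poly-A controls had a median of 5.28 on that array and the hybridization controls a median of 3.15. Of the 7 S. pombe ribosomal RNA probe sets, 2 had all 4 arrays labelled Spc1 or Spc1K49R above both empty-vector arrays, where chance gives 6.67% of probe sets, and 5 did not. The array labelled Spc1K49R replicate 2, whose sty1 value goes against its label, is 1 of these 4.

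The first pattern is that Spc1 replicate 1 stood apart from the other 5 arrays. Overexpression of Spc1 as its whole cause is argued against by the 1565 probe sets displaced by 1 or more on it. Over these the median signed value was -0.01 on Spc1 replicate 2, whose sty1 value was higher. It was 0.19 on empty vector replicate 1, the only positive value among the other 5 arrays, so a control array shared part of the displacement. Shortened RNA may have contributed, with a mean 5' minus 3' difference of -1.53, which is 4.0 SD below the mean of the other arrays. A small amount of sample RNA beside the added transcripts may have contributed too, with a hybridization control median of 3.15, which is 7.8 SD above the others. These technical explanations both remain open, as does an effect of Spc1 on part of the probe sets.

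The second pattern is the missing sty1 signal on the array labelled Spc1K49R replicate 2. A swap with an empty-vector array of this series is argued against, since the higher sty1 value of those arrays was -1.04. Poor RNA is argued against by a 5' minus 3' difference of 0.34, within the range of the other arrays. A wrong label and a culture that did not express the plasmid gene remain open and cannot be told apart. The other probe sets did not place the array with either group. The distance to Spc1K49R replicate 1 exceeded that to the nearer empty-vector array by 0.022, less than the spread of 0.098 between arrays. Its correlation across probe sets was 0.29 with empty vector replicate 2, -0.15 with empty vector replicate 1 and -0.14 with Spc1K49R replicate 1. Centring affects these correlations, so they do not place the array either.

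The third pattern is the higher value of the 7 named mating genes on the Spc1K49R arrays. The study picked these genes on these arrays, so neither their number nor their direction could be tested independently. They were 7 of the 21 S. pombe genes in the higher part of the table of mutant C against wild type. The gene table holds 23 genes of the mating list among 5124 protein-coding genes. Genes of 1 list are not independent draws on 2 arrays per group, so no test was drawn from this share. Selection of genes that happened to be low on the 2 empty-vector arrays is a candidate explanation. The median of Spc1 replicate 2 minus the empty-vector mean over the 7 genes was 0.34. For comparison, 10000 random sets of 7 other probe sets had the same order of arrays and a difference of 0.26 to 0.56. The central part of their medians covered 0.07 to 0.43. Those probe sets were not chosen by the study's p-values and were drawn independently, unlike genes of 1 list, so the comparison cannot decide. The 7 genes lay above both empty-vector arrays also on the array labelled Spc1K49R replicate 2, although sty1 was not raised there (-1.37). The study's selection of these genes on these arrays made that order nearly certain, and it rests on 1 array of doubtful label. Nothing can be read from it for or against an effect of overexpression. An effect of Spc1K49R, and an effect of overexpressing either form, therefore remain open.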

How the results depend on the processing

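The counts of 0 probe sets past the adjusted threshold held in all 3 comparisons under every alternative set before the data were examined that was run, except without Spc1 replicate 2. Over the arrays left out in turn the counts ranged from 0 to 2968 for Spc1 against empty vector, from 0 to 0 for Spc1K49R against empty vector and from 0 to 3234 for Spc1K49R against Spc1. The lone array is then assumed to vary like the other groups, which its SD of 0.82 goes against. Of alternatives chosen after seeing the data, removing both doubted arrays, the 5' minus 3' covariate and testing controls too gave 0, and an unadjusted p under 0.05 gave 108, 8 and 91, or 17, 92 and 33 with only the 4 arrays of the groups compared. The replicate number as a block gave 0, 0 and 0. Deviations of replicate 1 from the group mean correlated at 0.47 between empty vector and Spc1, 0.07 between empty vector and Spc1K49R and 0.10 between Spc1 and Spc1K49R, so the numbers were not taken to pair the arrays. The sty1 difference of Spc1K49R from empty vector ranged from -0.315 to 2.252 over the arrays left out, reversed without Spc1K49R replicate 1. The correlation of the 2 differences from empty vector, -0.05, became 0.43 and 0.32 without empty vector replicates 1 and 2, 0.64 without Spc1 replicate 1 and 0.02 without Spc1K49R replicate 2, and the cause was not tested. Of 1222 values of single named genes under alternatives, 1186 kept their direction and side of the threshold, and 36 passed it in the same direction, all 36 without Spc1 replicate 2. The groups of these genes do not overlap, which fixes their direction when an array is left out. Robust variances, array weights, the block and fits of only 4 arrays left the log2 differences as they were. Sizes were less stable. Of 94 named gene results, 26 moved over 1.5 times on leaving out 1 array and 28 with the 5' minus 3' covariate. Without the 2 doubted arrays 11 did. Quantile normalization over S. pombe probe sets, background centring on the other yeast, a dim filter, 1 probe set per gene, an intensity trend and the camera and fry alternatives were not run. Signal over background is unknown, since values were centred.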

Other observations

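The ura4 control probe sets, for a gene often used as a selection marker, differed little between arrays: the probe set at the 3' end ranged from -0.37 on Spc1 replicate 1 to 0.04 on Spc1 replicate 2. The S. pombe ribosomal RNA probe sets differed more between the empty-vector arrays, with a median of 0.06 on replicate 1 and -1.36 on replicate 2. For the 5' end of 18S ribosomal RNA, the empty-vector arrays had -0.67 and -1.23, and the other 4 lay between -0.09 and 0.34. This probe set, chosen after its values were seen, is 1 of 2 of the 7 that separated in this way, and over the 7 the empty-vector arrays differed from each other by a median of 1.23.

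At an unadjusted p under 0.05, 43 of the 173 control probe sets differed between Spc1 and empty vector, 6 between Spc1K49R and empty vector and 28 between Spc1K49R and Spc1. Groups that did not overlap made up 24.9%, 23.7% and 36.1% of probe sets in the comparisons of Spc1 with empty vector, Spc1K49R with empty vector and Spc1K49R with Spc1, where 33.3% is expected by chance.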
